A study of Mus musculus with 34 samples.

How the data were processed

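RNA of mouse liver and liver tumors was measured on Agilent whole mouse genome arrays (4x44K design) with 2 colors, the sample in Cy3 and a pooled liver reference of C57BL/6 mice of both sexes in Cy5. The 34 arrays fell into 10 groups by their labels (sizes in Results). The labels call each sample a biological replicate and give no sex. A sex score, the mean of Y-linked genes less Xist, ran from -4.23 to 7.15 over the arrays and was uneven between groups. Shifts of the sex-biased gene lists may therefore partly follow sex. Slide, scan day and scanner were read from the file headers. The scanner files hold the mean, background and processed intensity of each spot in both channels, where, per the file headers, the mean is scanner brightness and the processed intensity was background-subtracted, detrended and dye-normalized by Agilent Feature Extraction. Their log10 ratio of red over green was, per the file headers, made from these processed signals. The log2 values in the deposited series matrix were taken as log2 of red over green, since each column correlated with log2 of Cy5 over Cy3 at an r between 0.695 and 0.968 across genes, which are not independent replicates; the authors name limma in their processing notes with no version, and the background, dye and centring steps behind these values are not stated.

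From the scanner files, the mean signals of both channels were background-corrected by normexp with an offset of 50, log2 of Cy3 over Cy5 was normalized within each array by loess, and no scaling was applied between arrays. The work used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and version 1.17.8 of data.table. Control spots were left out, spots of the same probe were averaged, and spots that Feature Extraction marked as outliers were set to missing. A probe was kept if it was well above background in Cy3 on at least 3 of the 34 arrays, which kept 32773 of 41174 probes. Probes were named by their deposited transcript accession through RefSeq (27479 probes) or else by the symbol or name on the array file. Each gene was read at its kept probe with the highest mean signal, which gave 21819 genes, 7570 of them with more than 1 kept probe. A saturated spot or a group not well above background makes a fold a lower bound, written as at least.

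Groups were compared with limma (lmFit with 1 coefficient per group over all 34 arrays, eBayes), so that every comparison shares 1 estimate of the spread per gene, and the Benjamini-Hochberg adjusted p was taken over the genes tested in each comparison, with 0.05 as the threshold. There were 21 comparisons of 2 groups: tumors against controls, livers off a transgene against the tumors and against the controls, tumors against each other, and 12 against 4 weeks. Another 6 compared responses, off livers less tumors, as a difference of changes. Within a single day or slide, a group with 1 array was assumed to vary like the arrays of the other days and groups. Fold changes are on the log2 scale, first group minus second. How called genes divide into higher and lower moved by over 10 percentage points with the scaling in most comparisons, so these divisions hold for the scaling used.

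Before the data were examined, 38 gene lists were written from general knowledge and tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Counts of risen and fallen genes of a list use the adjusted p over all genes, and beside them the p adjusted over the list alone. With a correlation estimated from the arrays none of the list calls given here held. Another 8 tissue lists, written after the slide 5 arrays were seen to differ, were ranked by signal percentile in each channel.

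The rule for genes named in the text was fixed before the data were examined: Myc and Tgfa at every probe; in each comparison, among genes past the threshold whose groups do not overlap and which have a proper symbol, those with the 10 largest rises and the 10 largest falls; from each list whose count is given, up to 4 members with the smallest p; and for the responses the 5 smallest p on each side. The genes printed are a part of these, chosen after their values were seen. Counts written as kept or lost under a setting refer to the genes named for that comparison. 1 gene is not reported here.

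Alternatives were tried 1 at a time: no background subtraction, Agilent's processed signals, median centring, Aquantile scaling, the sample channel alone, the series matrix values, other filters and probe rules, outlier spots kept, eBayes with trend, array weights, only the groups compared, at least 2-fold, the replicate number as a block, slides as a random block (within-slide correlation 0.482), scan day as a fixed block, a sex score from Y-linked genes and Xist as a covariate, Myc tumors 3 and 4, whose names share a number, averaged, and leaving out each array. Chosen only after the data were seen were the fits without slide 5, without slide 5 and TGFα tumor 1, on the first scanner only, and with scanner or slide as a fixed block. Scan day as a block compares groups through arrays of the same day, and for comparisons of livers off TGFα or both transgenes for 4 weeks it links the groups only through slide 5. Overlaps of genes between comparisons that share arrays were set beside 20 simulations of unchanged groups.

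The procedure was tested on simulated data with planted changes. For Myc tumors against controls it found 25 of 67 genes changed 1.5-fold, 49 of 67 changed 2-fold and 64 of 66 changed 4-fold, with 2 false calls among 21819 genes. For 3 livers against 3 it found 15 of 67, 33 of 67 and 61 of 66, with 4 false calls. These counts are not the error rate of the real arrays, which correlate within slides (0.482).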

Results

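Gene expression was measured on 34 Agilent 2-color arrays of mouse liver RNA, and each value is log2 of sample over reference. The mice carried a c-Myc transgene, a TGFα transgene or both, and doxycycline turned the transgenes off. Tumors at end stage came from 7 c-Myc, 3 TGFα and 3 TGFα/c-Myc animals or tumors, labelled as biological replicates. The names of Myc tumors 3 and 4 share a number, so these are not shown to be of separate animals. Livers with the transgene off for 4 or for 12 weeks (3 in each of 6 groups) and 3 normal control livers made up the rest. The share of probes well above background in the sample channel ran from 43.7% (TGFα off 12 weeks replicate 3) to 71.8% (Myc tumor replicate 4), and the number of arrays limits the precision.

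The arrays lay on 16 slides scanned on 12 days, and Myc tumors 2 to 7 were read on a second scanner, on days that held no other group. Slide 5, scanned on a day of its own, held TGFα tumors 2 and 3 and TGFα off 4 weeks replicate 1. On these 3 arrays the plasma protein genes of hepatocytes had a median signal percentile of at most 69.6 in the reference channel, against at least 99.6 on the other 31 arrays. A list of intestine genes stood at 96.8 or above in that channel on slide 5 and at 54.0 or below elsewhere. The ratios on slide 5 therefore stand against a reference of another profile. The array of TGFα/c-Myc off 4 weeks replicate 3, alone on its slide and day, correlated across genes with its own group at a mean r of only 0.132, where genes are not independent replicates.

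**Figure D1:**
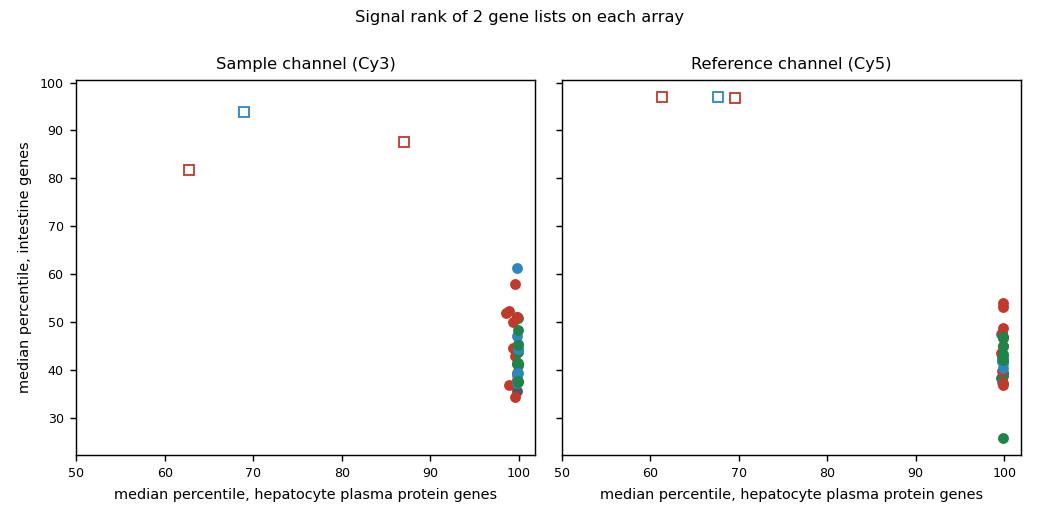
Median signal percentile of the plasma protein genes of hepatocytes (x axis, percent) and of the intestine genes (y axis, percent) on each of the 34 arrays, in the sample channel (left) and the reference channel (right). Points are arrays, colored grey for controls, red for tumors, blue for 4 weeks and green for 12 weeks off; the open squares are the 3 arrays of slide 5, whose intestine percentiles start at 81.7 in the sample channel against at most 61.2 on the other arrays.

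The transgenes' own genes were read at 3 Myc and 2 Tgfa probes. Myc probe A_52_P108346 stood at 4.58 ± 2.01 (SD, n = 7, a mean of at least this since tumor 1 was saturated) in the Myc tumors and at -0.26 ± 0.70 (n = 3) in the controls (limma adjusted p = 0.000327), and Myc probe A_52_P278549 at 3.20 ± 1.52 against 0.28 ± 0.32 (adjusted p = 0.00251). In TGFα/c-Myc tumors (n = 3) these probes stood at 3.65 ± 2.48 and 1.59 ± 1.48 (adjusted p = 0.106 and 0.640 against controls). Myc tumor 5, the lowest (1.04 and 0.10), and TGFα/c-Myc tumor 3 (0.83 and 0.07) lay above the controls at the first (at most 0.16). At the second both lay within the controls (-0.09 to 0.50), which leaves their label or transgene state in question. Off c-Myc, TGFα and both, Myc probe A_52_P108346 averaged 0.17, 0.32 and 1.01 at 4 weeks and 0.24, -0.16 and 0.12 at 12 weeks, and Myc probe A_52_P278549 averaged 0.16, 0.02 and 0.08, then -0.03, 0.06 and -0.06. Myc probe A_51_P102096 stood at -0.50 ± 0.46 in the Myc tumors and -0.20 ± 0.35 in the controls (adjusted p = 0.561). It was higher off both transgenes for 4 weeks than in the controls (1.43, SE 0.41, adjusted p = 0.0443), a call lost without control 2 (0.128), control 3 (0.216), off 4 weeks replicate 1 (0.195) or replicate 2 (0.125). The array labelled TGFα tumor 1 read at least 3.28 (saturated) and 3.55 at the first 2 Myc probes, while TGFα tumors 2 and 3 read between -0.09 and 0.21, so the label of that array stands in question in every TGFα tumor comparison. Tgfa probe A_51_P415126 stood at -0.17 ± 0.22 in the TGFα tumors and -0.40 ± 0.27 in the controls (adjusted p = 0.684), and Tgfa probe A_52_P555423 at 0.12 ± 0.20 and 0.23 ± 0.06 (adjusted p = 0.733). Whether these Tgfa probes lie within the transgene's transcript is not given in the sources used here.

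**Figure D2:**
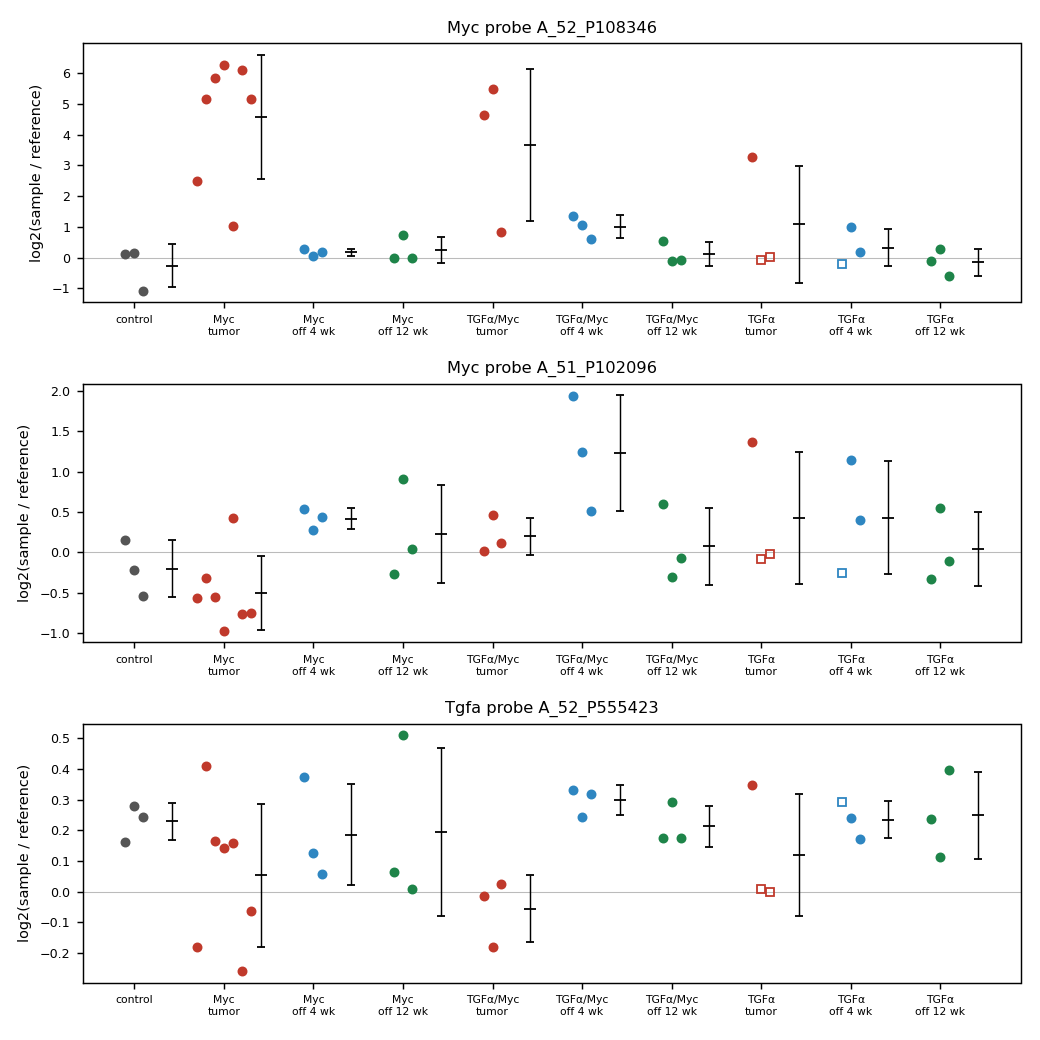
Log2 of sample over reference (y axis) at Myc probes A_52_P108346 and A_51_P102096 and Tgfa probe A_52_P555423 in each group (x axis). Points are arrays, open squares the arrays of slide 5, and the black bars show mean ± SD; at Myc probe A_52_P108346 the Myc tumors averaged at least 4.58 and the array labelled TGFα tumor 1 stood at 3.28 or more, with Myc tumor 1 and this array saturated.

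The first comparison asked how c-Myc tumors (n = 7) differ from control liver (n = 3). Afp, the alpha-fetoprotein gene of fetal liver and liver tumors (probe A_51_P510891), stood at 6.64 ± 1.97 (SD) in the tumors and -0.28 ± 0.33 in the controls, a log2 difference of 6.91 (SE 0.92, adjusted p = 7.45e-06). Asns, which makes asparagine, was higher by 6.58 (SE 0.83, adjusted p = 4.38e-06) and Psat1, of serine synthesis, by 5.38. S100g, a calcium-binding protein gene, was higher by 5.81 and the acetyl-CoA synthetase gene Acss1 by 5.72. Scd2, a fatty acid desaturase gene, was higher by 5.57 and Igfbp1 by 5.37. H19 and the RNA-binding protein gene Igf2bp3, both of fetal liver, were higher by 3.19 and 3.85. In all, 11 of 19 measured oncofetal and liver tumor markers rose, 1 fell and 7 were not called (12 and 1 adjusted over the list alone, camera adjusted p = 0.000191, or adjusted p = 0.468 with an estimated correlation).

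Genes of cell division and growth rose together in the Myc tumors. Of the cell cycle and mitosis list 27 of 28 genes rose, of DNA replication 23 of 24, and of ribosome biogenesis 17 of 25. Nucleotide, polyamine and folate synthesis had 13 of 18 risen, glycolysis enzymes of the non-hepatic type 10 of 13 and p53 target genes 9 of 15, and none of these 6 lists had a fallen gene. Adjusted over the list alone, the risen genes were 27, 23, 23, 14, 13 and 9. The camera adjusted p ran from 2.69e-14 for the cell cycle to 7.80e-05 for p53 targets, and each was 0.468 with an estimated correlation. Birc5, which encodes survivin, was higher by 4.48 (SE 0.79, adjusted p = 0.000145), the helicase gene Mcm6 by 4.36, Npm1 by 2.22, Cdk1 by 2.13 and Impdh2, of guanine nucleotide synthesis, by 2.12. Tumor 5, in question above, had Birc5 at 0.10 (others 3.26 to 4.96), Cdk1 at 0.10 and Mcm6 at -0.04.

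Genes of mature hepatocytes fell. The major urinary protein gene Mup5 was lower by 8.07 on the log2 scale (-8.07, SE 1.39, adjusted p = 0.000118), and Mup1, saturated in the controls, was at least 142-fold lower (adjusted p = 0.000264). Ces3b, a carboxylesterase, changed by -6.31, the organic anion transporter gene Slc22a7 by -5.81, Cyp7b1 of bile acid synthesis by -5.47 and the glucuronosyltransferase gene Ugt2b1 by -5.36. Ntrk2, which encodes a neurotrophin receptor, changed by -5.84 (SE 0.75, adjusted p = 5.81e-06, 3 of 3 probes). Of drug and steroid metabolism 13 of 22 genes fell, with Cyp1a2 at -3.63. Male-biased liver genes had 12 of 18 fallen, plasma protein genes 10 of 19 with Apoc3 at -3.97, bile acid synthesis and transport 10 of 17, and urea cycle and amino acid catabolism 8 of 23. None of these 5 lists had a risen gene, and adjusted over the list alone 13, 13, 14, 11 and 8 genes fell. Camera gave adjusted p values from 1.51e-06 to 0.000201, and from 0.468 to 0.502 with an estimated correlation. The ERK feedback gene Phlda1 changed by -5.00 and Ccnd1, which encodes cyclin D1, by -2.74.

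Inflammatory and non-parenchymal genes also differed in the Myc tumors. Lcn2 was higher by 3.04, the serum amyloid gene Saa3 by 3.54 and the interferon response gene Usp18 by 2.66. Neutrophil markers had 4 of 10 genes risen (5 adjusted over the list alone, camera adjusted p = 0.0357, 0.546 with an estimated correlation), a direction that turned with scan day or scanner as a block. Endothelial markers had 5 of 14 fallen and 2 risen (7 and 2 adjusted over the list alone, adjusted p = 0.0439, 0.522 with an estimated correlation), a call that ended with slides as a random block (adjusted p = 0.0851). Per1 was higher by 1.60 and Dbp, another clock gene, changed by -3.23. In all, 7212 of 21819 genes passed, 3770 higher and 3442 lower, and 4721 passed without control 3. With scan day as a block 4030 passed and with slides as a random block 7090, and on day 1, with 1 tumor and 1 control, 4026 differed, with cell cycle and plasma protein medians of 2.95 and -0.92. Of 30 genes followed under every setting, the scan day block kept 22 calls and turned Saa3 to -0.32, the scanner block kept 20, and median centring left 2893 genes in all.

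**Figure D3:**
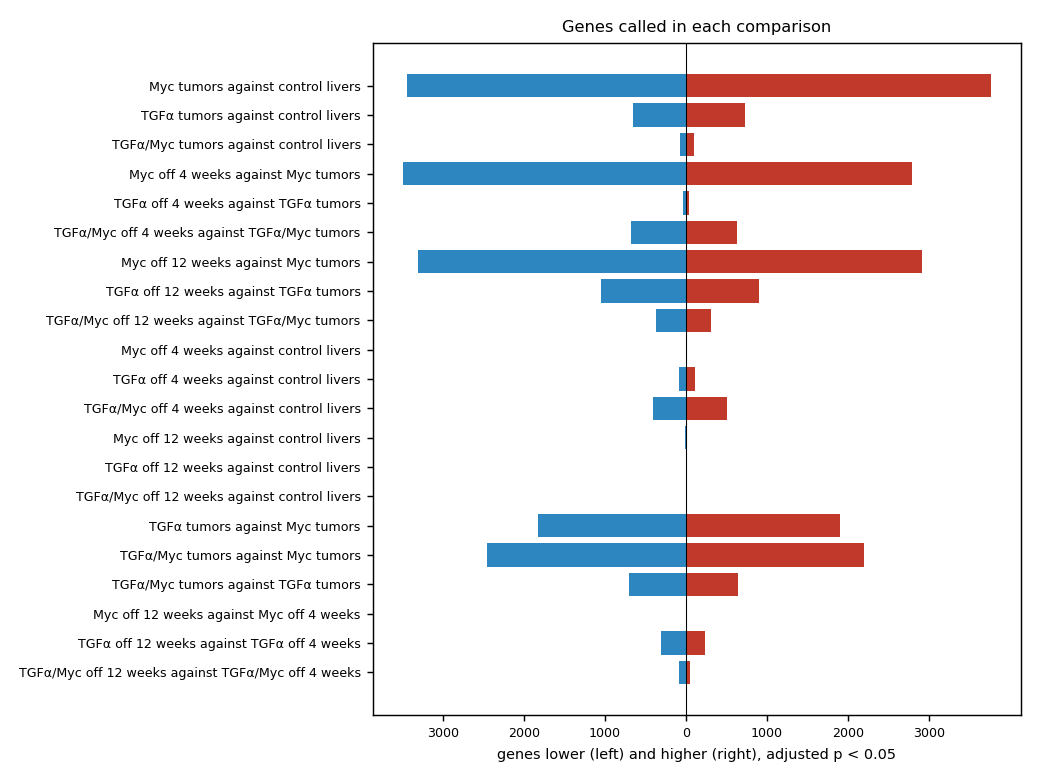
Number of genes past an adjusted p of 0.05 (x axis) that were lower (left, blue) or higher (right, red) in the first group named, for each comparison of 2 groups (y axis). The Myc tumors had 3770 genes higher and 3442 lower than the controls, and livers off c-Myc for 4 weeks had 1 of each.

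Livers off c-Myc for 4 weeks (n = 3) largely lacked the tumor profile. By label off samples are livers, not tumors, so tissue and transgene loss cannot be told apart, in the responses too. Against the tumors, Afp changed by -6.86 (SE 0.92, adjusted p = 1.41e-05), Asns by -5.73, S100g by -5.47, Psat1 by -5.25 and Phgdh, the first enzyme of serine synthesis, by -4.80. The sulfotransferase gene Sult2a8 was higher by 5.58, Ces3b by 5.82, Ugt2b1 by 5.42 and Mup1 by 7.66 (adjusted p = 0.000507). Cell cycle genes fell in 27 of 28 cases, DNA replication genes in 22 of 24 and ribosome biogenesis genes in 20 of 25, and 10 of 19 oncofetal markers fell with 1 risen. Of drug and steroid metabolism 15 of 22 genes rose, of the male-biased list 12 of 18, of plasma proteins 12 of 19 and of the urea cycle list 14 of 23, and 6 of 14 circadian clock genes rose with 1 fallen. Adjusted over the list alone the counts were 27, 23, 22 and 10 fallen, and 18, 12, 14, 15 and 6 risen. For these lists the camera adjusted p ran from 6.03e-14 to 0.00360 and was 0.322 for each list with an estimated correlation. In all, 6294 genes passed (2796 higher, 3498 lower), 5990 with scan day as a block and 6695 with slides as a random block. Day 1 alone, with 3 livers and 1 tumor, gave 5988, slide 1 with 1 of each gave 3700, 3890 passed without off 4 weeks replicate 1 and 4131 without replicate 2. The clock list's call ended with scan day as a block (adjusted p = 0.0895).

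At 12 weeks off (n = 3) against the Myc tumors, Afp changed by -6.68 (SE 0.92, adjusted p = 1.47e-05), Asns by -6.23, Scd2 by -5.34, Phgdh by -5.30 and Gsn, which encodes gelsolin, by -4.75. Ugt2b1 was higher by 5.77, and the sulfotransferase gene Sult3a1, not well above background in the tumors, by at least 134-fold (adjusted p = 0.0109). All 28 cell cycle genes, 21 of 25 ribosome biogenesis genes and 12 of 19 oncofetal markers fell, with 1 such marker risen. Urea cycle and amino acid catabolism had 17 of 23 genes risen, drug and steroid metabolism 12 of 22 and the female-biased list 10 of 18. Adjusted over the list alone these were 28, 24 and 12 fallen, and 19, 13 and 11 risen. The camera adjusted p ran from 3.28e-16 to 0.000157, and from 0.247 to 0.468 with an estimated correlation. In all, 6222 genes passed (2917 higher, 3305 lower), but 278 with scan day as a block, where of 7 genes followed only Asns kept its call. No day held Myc tumors and 12-week livers together.

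Of 3770 genes higher in Myc tumors 2935 were lower off c-Myc at 4 weeks and 2582 at 12. Of 3442 lower genes 2234 and 2064 were higher. Independent lists would share 604, 571, 441 and 460. Simulated unchanged groups with the same shared tumor arrays shared 0, near given with nothing changed. The log2 changes had a covariance of -0.629 and -0.617 against -0.0192 and -0.0193 simulated (r -0.95 and -0.90 against -0.29). Tumors 1 to 4 were then used in the first comparison and 5 to 7 in the second. Of 4062 risen genes 1931 and 1611 were lower (independent 425 and 371). Of 3364 fallen genes 1484 and 1463 were higher (independent 301 and 315), with r of -0.89 and -0.85.

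**Figure D4:**
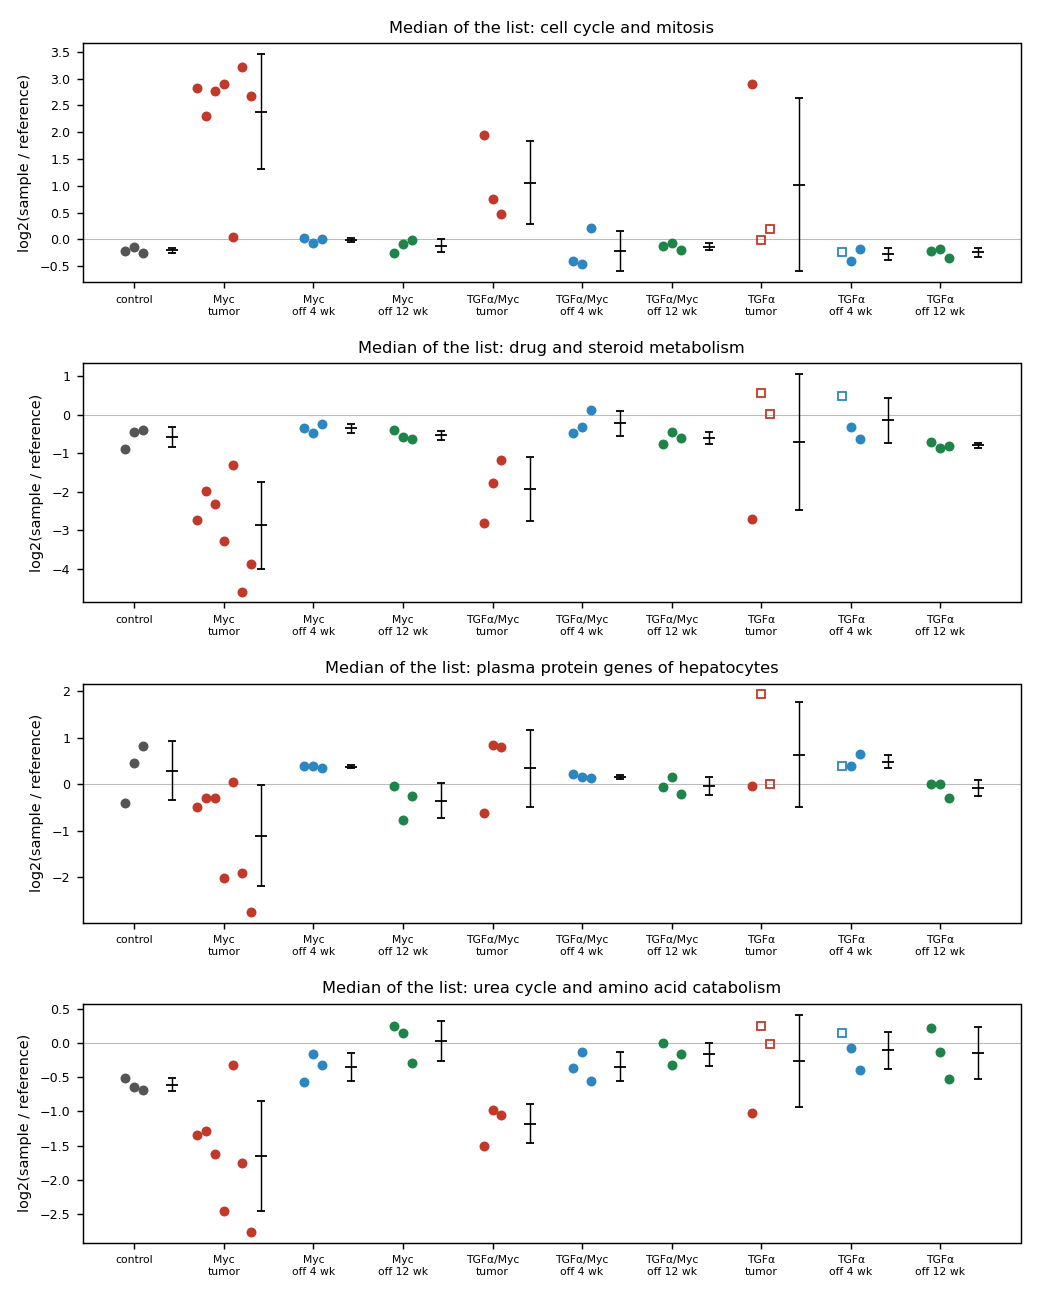
Median log2 of sample over reference (y axis) of 4 gene lists on each array, by group (x axis). Points are arrays, open squares the arrays of slide 5 and black bars mean ± SD; the cell cycle median of Myc tumor 5 lies at 0.04 and that of the array labelled TGFα tumor 1 at 2.89.

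Few genes separated the livers off c-Myc from the controls (n = 3 each). At 4 weeks 2 of 21819 genes passed, Per1 higher by 1.91 (SE 0.25, adjusted p = 0.00117, higher in 3 of 3 livers than in any control) and Homez, a homeobox gene, at -0.65, with 798 genes at an unadjusted p under 0.05. Immediate early genes and stellate cell and extracellular matrix genes had no called member, yet their lists shifted up (camera adjusted p = 8.99e-09 and 2.49e-07, each 0.553 with an estimated correlation), with 2 of 13 and 4 of 20 risen adjusted over the list alone. At 12 weeks 19 genes passed, 12 higher and 7 lower. Per1 was higher by 1.69 (SE 0.25, adjusted p = 0.00928), the clock-related genes Usp2 and Noct by 2.50 and 2.46 and the amino acid transporter gene Slc38a2 by 1.79, while the acyl-CoA synthetase gene Acsm2 changed by -1.89. Female-biased liver genes shifted up with no called gene (1 adjusted over the list alone, adjusted p = 0.00212, 0.979 with an estimated correlation), a call that ended with the arrays' sex score as a covariate, and the clock list had 1 of 14 risen (2 adjusted over the list alone, adjusted p = 0.0216, 0.979 with an estimated correlation). At 4 weeks 15 genes passed with scan day as a block, 15 within day 1 and 14 within slide 2; at 12 weeks 16 passed with the block and 16 within day 7, and none of the 5 genes and 2 lists named kept its call with the block. At 4 weeks 1 gene passed without control 3, off 4 weeks replicate 1 or replicate 2. At 12 weeks 0 passed without control 3 or off 12 weeks replicate 1, 1 without control 2 or off 12 weeks replicate 2, 72 without replicate 3 and 313 without control 1.

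Between 4 and 12 weeks off c-Myc 1 gene passed, Shtn1 at -1.21 (adjusted p = 0.038), named after its value was seen, with 1330 genes at an unadjusted p under 0.05. Stellate cell and extracellular matrix genes shifted down (0 of 20 called, 3 fallen adjusted over the list alone, camera adjusted p = 4.50e-05, 0.939 with an estimated correlation), and this list's call ended with scan day as a block. Leaving out off 4 weeks replicates 1 or 2 or off 12 weeks replicates 1 or 2 left 0 genes, and leaving out off 12 weeks replicate 3 gave 6.

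In the TGFα/c-Myc tumors (n = 3) against the controls (n = 3), Phgdh of serine synthesis and Asns of asparagine synthesis were again higher. Phgdh stood at 5.12 ± 0.73 (SD) against 0.62 ± 0.53 (adjusted p = 0.0146), Asns was higher by 4.49 (SE 0.98, adjusted p = 0.0281) and Igfbp1 by 4.65. The mitosis genes Cdc20 and Birc5 were higher by 4.17 and 3.97, the lipase gene Lpl by 3.51, the peptidyl-prolyl isomerase gene Fkbp11 by 3.45 and the fetal growth factor gene Igf2 by 3.15. Ntrk2 changed by -4.38 (SE 0.88, adjusted p = 0.0196), Phlda1 by -2.74, the acute phase gene Orm1 by -2.58, Insig1, a regulator of sterol synthesis, by -2.14, Acsm2 by -1.96 and the fatty acid elongase gene Elovl5 by -1.95. Of cell cycle genes 4 of 28 rose, of ribosome biogenesis genes 2 of 25, of oncofetal markers 2 of 19 and of DNA replication genes 0 of 24. Of cholesterol synthesis genes 2 of 16 fell, of fatty acid synthesis genes 1 of 13 and of urea cycle and amino acid catabolism genes 0 of 23. Adjusted over the list alone 11, 8, 7 and 5 rose and 3, 3 and 2 fell. Camera gave adjusted p values from 4.73e-14 to 0.00126, and from 0.455 to 0.576 with an estimated correlation. In all, 166 genes passed (96 higher, 70 lower), none with only these groups fitted and 864 with scan day as a block. Slides as a random block left 3, with none of the 14 genes named here. Without TGFα/c-Myc tumor 1 3 passed, without control 2 5, without control 3 20, without control 1 65, without tumor 2 88 and without tumor 3 469. The array labelled TGFα tumor 1 shared a slide with tumor 3.

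Livers off both transgenes for 4 weeks (n = 3) were set against those tumors (n = 3). Phgdh changed by -5.21 (SE 0.85, adjusted p = 0.00106), Cdc20 by -4.55, Tff3 by -4.22, Afp by -4.12, Birc5 by -4.05, Fkbp11 by -3.52 and Sprr2b by -3.38. The acute phase gene Saa2, saturated off the transgenes, was at least 31.5-fold higher (adjusted p = 0.00924), Orm1 was higher by 3.35, Orm2 by 3.09 and Saa3 by 3.00. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was higher by 3.08 and Thrsp, a lipogenic regulator, by 2.91. Of the acute phase list 7 of 17 genes rose, of cholesterol synthesis 3 of 16 and of drug and steroid metabolism 2 of 22. Of the cell cycle list 9 of 28 fell, of oncofetal markers 5 of 19 and of endoplasmic reticulum stress genes 4 of 15 with 2 risen. All but the acute phase and stress lists turned direction with scan day as a block. Adjusted over the list alone 8, 5 and 6 rose and 13, 8 and 9 fell, with 1 acute phase gene fallen and 2 stress genes risen. For these lists the camera adjusted p ran from 9.96e-11 to 0.0170, and from 0.518 to 0.571 with an estimated correlation. In all, 1311 genes passed (636 higher, 675 lower), 489 with scan day as a block, which ties the groups only through slide 5 and kept none of the 13 genes named, turning Afp to 2.19, Tff3 to 1.39 and Fkbp11 to 0.86. With slides as a random block 398 passed, without tumor 1 308, without off 4 weeks replicate 2 647 and without tumor 2 731.

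At 12 weeks off both transgenes (n = 3) Thrsp was higher than in the tumors by 3.83 (SE 0.42, adjusted p = 1.51e-05), Cyp2e1 by 3.70, Cyp7a1 by 3.06, the fatty acid desaturase gene Fads1 by 2.81 and Acss2, of acetyl-CoA synthesis, by 2.53. Phgdh changed by -5.05, Cdc20 by -4.59, Birc5 by -4.04 and Afp by -4.03. Fatty acid and cholesterol synthesis each had 3 genes risen, of 13 and 16, and urea cycle and amino acid catabolism 4 of 23. Cell cycle genes fell in 8 of 28 cases, oncofetal markers in 4 of 19 and ribosome biogenesis genes in 3 of 25. Adjusted over the list alone 5, 7 and 8 rose and 11, 10 and 8 fell. The camera adjusted p ran from 4.90e-13 to 3.33e-08, and from 0.183 to 0.463 with an estimated correlation. In all, 678 genes passed (312 higher, 366 lower), 475 with scan day as a block and 16 with slides as a random block, where 1 of 9 named genes kept its call. Without tumors 1, 2 and 3 in turn 98, 413 and 1243 passed, and without the 12-week livers in turn 127, 162 and 149. Of the 96 risen and 70 fallen tumor genes, 62 and 26 reversed sign at 4 weeks and 69 and 33 at 12 weeks. Independent lists share at most 3. The covariances were -0.156 and -0.169 against -0.0461 simulated (r -0.65 and -0.76 against -0.50), and part of the excess may come from the shared tumors, which are too few to split.

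**Figure D5:**
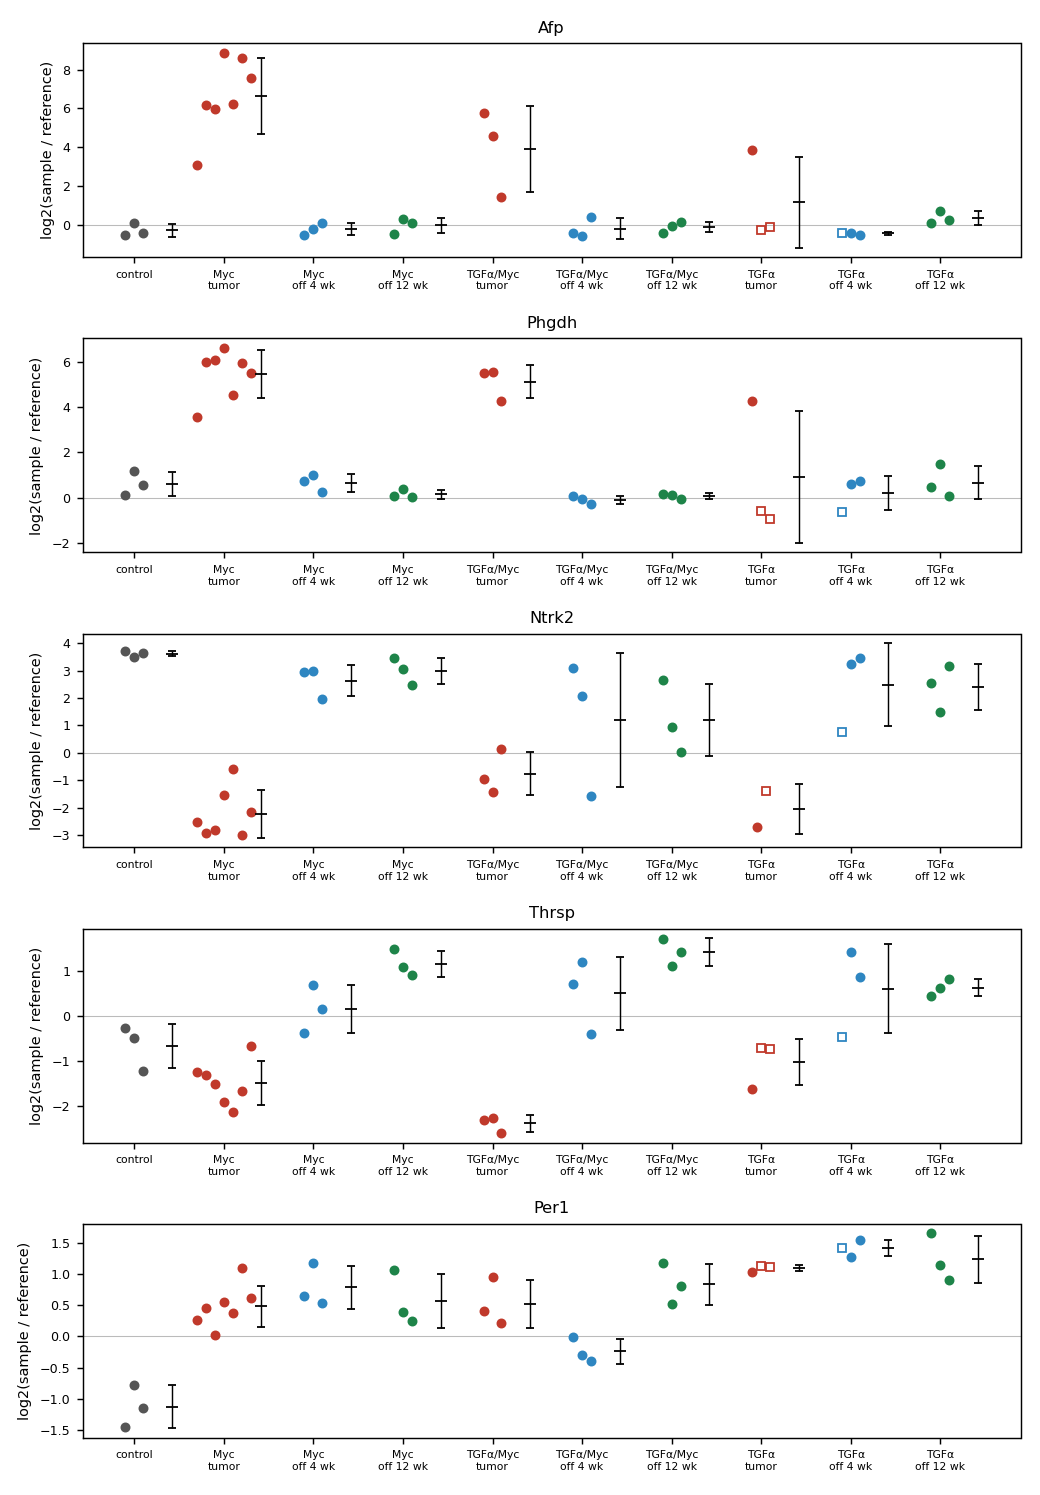
Log2 of sample over reference (y axis) of Afp, Phgdh, Ntrk2, Thrsp and Per1 in each group (x axis). Points are arrays, open squares the arrays of slide 5 and black bars mean ± SD; Per1 lies between -1.45 and -0.77 in the controls and between -0.40 and 1.65 on the other 31 arrays.

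Against the controls, livers off both transgenes for 4 weeks had 910 genes past the threshold (508 higher, 402 lower). None passed with only these groups fitted or in the sample channel alone, and few with median centring. Saa3 was higher by 2.74 (SE 0.66, adjusted p = 0.0199), the phosphatidate phosphatase gene Lpin1 by 2.31, Alas1 of heme synthesis by 2.08, the fatty acid uptake gene Cd36 by 2.00 and Nampt of NAD synthesis by 1.92. Cyp26b1, which degrades retinoic acid, changed by -2.93, Acsm2 by -2.25 and the p53 target Bbc3 by -1.74. Acute phase genes had 2 of 17 risen, also adjusted over the list alone (camera adjusted p = 0.0326, 0.952 with an estimated correlation), and turned direction with scan day as a block. With that block, tied only through slide 5, 940 genes passed but 1 of the 8 named genes kept its call and Bbc3 turned to 1.01; slides as a random block left 535, and 161, 240 and 262 passed without control 3, off 4 weeks replicate 2 and control 2. At 12 weeks 2 genes passed, Per1 higher by 1.96 (SE 0.25, adjusted p = 0.000734) and the actin regulator gene Mical2 at -1.56 (1 of 2 probes), with 1853 at an unadjusted p under 0.05. The clock list had 1 of 14 risen (2 adjusted over the list alone, adjusted p = 0.00256, 0.506 with an estimated correlation). At 12 weeks no gene passed with slides as a random block, 26 passed without control 1 and 1 without control 2, control 3 or off 12 weeks replicate 3. From 4 to 12 weeks 138 genes passed (55 higher, 83 lower), with Trib3 of the stress response higher by 2.12 (SE 0.49, adjusted p = 0.0430), Plekhf1 by 1.22 and Desi2 at -1.57. With slides as a random block 2 passed, without off 4 weeks replicate 3 435, and without any other of these livers between 6 and 18.

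The TGFα comparisons rest on 2 tumors and 1 liver of slide 5 and on the array labelled TGFα tumor 1. Without slide 5 that array of doubtful label is the only TGFα tumor (n = 1), with the spread taken from the other groups, so counts without slide 5 say little of TGFα tumors. Against the controls (n = 3 each), Igfbp1 was higher in the TGFα tumors by 4.03 (SE 1.09, adjusted p = 0.0264), Anxa5 by 2.87, Txnip by 2.51, the immediate early gene Fos by 2.38, Btg3 by 2.28 and Cd36 by 2.26. Ntrk2 changed by -5.67 (n = 2 tumors with a value), Fabp2 by -4.12, Sis, which encodes sucrase-isomaltase, by -3.75 and the bile acid transporter gene Slc10a2 by -3.56; the last 3 are intestine genes and lost their call without slide 5, as did Cd36. Igfbp1 and Sis turned to -2.11 and 1.42 in the sample channel alone. Immediate early genes had 3 of 13 risen (6 adjusted over the list alone, camera adjusted p = 0.000189), and cell cycle genes 0 of 28 (0 adjusted over the list alone, adjusted p = 7.15e-06), both 0.847 with an estimated correlation and both not called without TGFα tumor 1. In all, 1391 genes passed (731 higher, 660 lower), few with only these groups fitted. Scan day as a block gave 2196 and slides as a random block 552. Without control 3 101 passed, without TGFα tumors 3 and 2 550 and 605, and without control 2 803.

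Against the TGFα tumors, livers off TGFα for 4 weeks (n = 3) had 75 genes past the threshold (41 higher, 34 lower). Ntrk2 was higher by 4.54 (SE 0.99, adjusted p = 0.0368), Ces1g by 3.74 and Cyp2c65 by 3.26, while Mfsd4a changed by -1.60 and Pde7a by -1.49. Cell cycle genes shifted down (0 of 28 called, 0 adjusted over the list alone, adjusted p = 6.40e-13, 0.611 with an estimated correlation), a call lost without TGFα tumor 1, and fatty acid oxidation genes up (0 of 21 called, 4 adjusted over the list alone, adjusted p = 1.35e-09, 0.246 with an estimated correlation). Without slide 5 (n = 1 tumor) 981 genes passed, within slide 5 655 and with scan day as a block 667, while 309, 251, 15 and 7 passed without TGFα tumor 1, off 4 weeks replicate 1, and tumors 2 and 3. At 12 weeks (n = 3) 1953 passed (904 higher, 1049 lower), with Ntrk2 higher by 4.45, the angiogenin gene Ang by 4.44 (SE 0.82, adjusted p = 0.00229) and Fabp2 by 3.50, and Anxa5 at -2.47 and the chaperonin gene Cct4 at -2.38. Of cell cycle genes 2 of 28 fell, the same number adjusted over the list alone (camera adjusted p = 5.27e-06, 0.937 with an estimated correlation), again not called without TGFα tumor 1. With scan day as a block 737 passed and none of these 5 genes, with slides as a random block 84, and between 885 and 1193 without TGFα tumors 2 or 3 or any of the 12-week livers.

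Against the controls, 205 genes passed at 4 weeks off TGFα (118 higher, 87 lower) and 5 at 12 weeks. Per1 was higher by 2.54 (SE 0.25, adjusted p = 4.28e-06) at 4 weeks and by 2.36 at 12 weeks. The clock output genes Ciart, Noct and Usp2 were higher at 4 weeks by 2.71, 2.44 and 2.43 and Alas1 by 2.56, while Acsm2 changed by -2.28 and the kinase gene Nuak2 by -1.58. At 12 weeks Acsm2 changed by -1.85, Hipk2 by -1.04 (2 of 4 probes) and AK051538, named after its value was seen, by 0.54, while Rab8a stood at -0.40 ± 0.03 against 0.59 ± 0.34 (adjusted p = 0.0439), with 1502 genes at an unadjusted p under 0.05. The clock list shifted up at both times, with 1 of 14 called each and 4 and 2 adjusted over the list alone (adjusted p = 0.00797 and 0.00219, 0.878 and 0.693 with an estimated correlation), female-biased genes at 4 weeks (0 of 18, 0 adjusted over the list alone, adjusted p = 0.000226, 0.878 with an estimated correlation) and p53 targets at 12 weeks (0 of 15, 4 adjusted over the list alone, adjusted p = 0.00129, 0.992 with an estimated correlation). Scan day as a block ended all 4 list calls and turned both at 4 weeks; at 4 weeks it passed 1141 genes, slides as a random block 110, and 570, 326, 32, 18 and 1 passed without control 1, off 4 weeks replicate 3, control 2, off 4 weeks replicate 2 and control 3. At 12 weeks 21 passed without control 1, 2 without off 12 weeks replicate 1 and 1 without control 2, control 3 or off 12 weeks replicate 2. From 4 to 12 weeks 544 passed (233 higher, 311 lower), with Neat1 higher by 1.96 (SE 0.37, adjusted p = 0.00801), Ugt1a1 at -2.78 and Rdh10 at -2.29 (0.04 with scan day as a block). None passed with slides as a random block, 216 without slide 5, and between 138 and 183 without off 4 weeks replicates 1 or 2 or any 12-week liver.

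The tumors of different transgenes were compared with each other. TGFα/c-Myc tumors (n = 3) had Ido2 higher than Myc tumors (n = 7) by 4.26, Egfr, the receptor of TGFα, by 3.94 (SE 0.71, adjusted p = 0.000443, 6 of 6 probes), Apoc3 by 3.62 and Slc16a11 by 3.52. S100g changed by -4.78, Saa3 by -3.80, Igf2bp3 by -3.34 and the neutrophil gene S100a8 by -3.33. Plasma protein genes rose in 10 of 19 cases (13 risen and 1 fallen adjusted over the list alone), and glycolysis genes of the non-hepatic type fell in 9 of 13 (9). Cell cycle genes fell in 12 of 28 (13), a direction that turned with Agilent's processed signals, the sample channel alone or the series matrix values, and acute phase genes fell in 10 of 17 with 3 risen (10 and 3), which turned with the scan day or scanner block. Camera gave adjusted p values from 3.90e-05 to 0.0134, and from 0.792 to 0.846 with an estimated correlation. In all, 4662 genes passed (2199 higher, 2463 lower), but 631 with scan day as a block, which kept 1 of 8 named genes and turned Saa3 to 1.18 and S100a8 to 0.07, and 1428 without TGFα/c-Myc tumor 2. No day or slide held both kinds of tumor. Of genes that rose or fell in Myc tumors against controls, 88 and 49 did so in TGFα/c-Myc tumors (independent 17 and 11). The covariance was 0.257 against 0.0458 simulated (r 0.66 against 0.59), and part of this may come from the shared controls.

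TGFα tumors differed from Myc tumors in 3733 genes (1901 higher, 1832 lower), but in 81 without slide 5, where the array labelled TGFα tumor 1 stands alone and resembles Myc tumors, and in 36 with scan day as a block, where none of the 7 genes named next kept its call. Hrg was higher by 4.22, Mbl2 by 4.12, C9 by 4.11 and Egfr by 4.11 (SE 0.71, adjusted p = 0.000593), while the intestinal lectin gene Reg3g changed by -4.18, Adam8 by -3.85 and Lgals3 by -2.62; Hrg, Mbl2, C9, Reg3g and Lgals3 turned direction in the sample channel alone. Plasma protein genes rose in 15 of 19 cases and drug and steroid metabolism in 13 of 22, while cell cycle genes fell in 11 of 28, all 3 turning direction in the sample channel alone (15, 20 and 17 adjusted over the list alone; adjusted p = 1.08e-07, 2.51e-10 and 2.39e-08, and 0.347, 0.245 and 0.439 with an estimated correlation). Without TGFα tumors 1, 2 and 3 in turn 6756, 626 and 769 genes passed. TGFα/c-Myc and TGFα tumors differed in 1350 genes (647 higher, 703 lower), 637 without slide 5 (n = 1 TGFα tumor), with Phgdh higher in the former by 4.21 (SE 0.85, adjusted p = 0.00460), Fabp2 by 4.01, Fkbp11 by 3.30 and Fgf21 by 2.75, and Orm1 at -2.82, Gnmt at -2.59 and Bnip3 at -2.42. Against that array alone 1 of these 7 genes kept its call, and Orm1, Gnmt and Bnip3 turned direction in the sample channel alone. The urea cycle list had 5 of 23 fallen and 2 risen (12 and 2 adjusted over the list alone, adjusted p = 0.000705, 0.787 with an estimated correlation) and also turned in the sample channel alone. On day 3 alone, with 1 tumor each, 82.6% of the 1350 genes had the same sign. Scan day as a block gave 1576 genes and slides as a random block 730. Without TGFα tumors 1, 2 and 3 in turn 2907, 318 and 327 passed, and without TGFα/c-Myc tumors 1, 2 and 3 517, 400 and 2055.

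Whether the response off the transgene differed between the transgenes was tested as a difference of changes. At 4 weeks TGFα/c-Myc and c-Myc responses differed in 2393 genes (1246 higher, 1147 lower): Rabggtb changed by 0.69 against -1.65, a difference of 2.35 (SE 0.28, adjusted p = 6.10e-05), Sdhd of the respiratory chain by 1.06 against -1.80 and Blcap by -0.95 against 1.32. Of acute phase genes 9 of 17 responded more upward and 1 downward (10 and 3 adjusted over the list alone, camera adjusted p = 0.00487, 0.976 with an estimated correlation), and of male-biased genes 3 of 18 more downward (9, adjusted p = 0.000127, 0.976 with an estimated correlation). At 12 weeks these responses differed in 329 genes (174 higher, 155 lower), with Clta of the clathrin coat at 1.04 against -0.79 and Slc16a11 at -1.32 against 2.29. The TGFα and c-Myc responses differed in 129 genes at 4 weeks (34 higher, 95 lower), with Ccl6 at 0.32 against -2.83, and in 1148 at 12 weeks (756 of them lower), with Efr3a at -0.86 against 0.67, and without slide 5, where the TGFα response starts from the array labelled TGFα tumor 1 alone, in 17 and 25. The TGFα/c-Myc and TGFα responses differed in 27 genes at 4 weeks (10 higher, 17 lower), with Sars, a seryl-tRNA synthetase gene, at -2.14 against 0.02, and in 1096 at 12 weeks (580 higher, 516 lower), with Atraid at 1.78 against -1.13. With scan day as a block, in the same order, 4266, 115, 2419, 25, 619 and 1088 genes differed, and with slides as a random block 3170, 330, 769, 12, 169 and 0. Without slide 5 scan day could not be fitted for the differences with 4266 and 2419, so both rest on that slide. Median centring left almost none at 4 weeks. Leaving out 1 array gave, in the same order, lowest counts of 1163, 25, 0, 29, 3 and 379. Highest counts for the last 5 were 1211 (Myc tumor 5), 2557, 4281, 756 and 2429, the last 4 without TGFα tumor 1.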

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

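Chosen only after the results were seen were the tests on slide 5, on Per1, and of a TGFα tumor with its own Myc expression; of the wrong-label tests of the array labelled TGFα tumor 1, both written before, that for a Myc tumor had its condition changed after its result was seen. Among 104 tests of a single Myc tumor lying far from the other 6, 9 values did, where chance gives about 1 in 20. Tumor 5 stood low at Birc5 (0.10, others 3.26 to 4.96), Cdk1 (0.10, others 1.71 to 2.38), Mcm6 (-0.04, others 2.89 to 4.47) and Fkbp11 (1.16, others 2.48 to 2.93). Tumor 1 stood apart at Slc22a7 (-1.03, others -4.83 to -3.26), Igf2 (1.32, others 2.99 to 4.23), Saa2 (-1.41, others 1.36 to 3.27) and Sprr2b (1.46, others -0.56 to -0.09), and tumor 4 at Mfsd4a (0.46, others -0.06 to 0.16). The responses to transgene loss differed between transgenes by the test of the difference itself, in 129 genes (TGFα less Myc), 2393 (TGFα/c-Myc less Myc) and 27 (TGFα/c-Myc less TGFα) at 4 weeks and in 1148, 329 and 1096 at 12 weeks.

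On slide 5 the plasma protein genes had low signal in both channels. Against weak hybridisation, the lowest share of probes well above background there was 63.5%, inside the 43.7% to 71.4% of the other arrays of that scanner, and against a loss of hepatocyte expression in the tumors, the reference channel too had these genes at a percentile of at most 69.6, where the other 31 arrays had 99.6 or more. A list of 18 intestine genes (17 on the array, 5 of them seen beforehand) had a percentile of at least 81.7 over both channels, against at most 61.2 elsewhere, and the 12 measured genes not seen beforehand at least 83.4 against 46.8 in the sample channel. Signals in the sample channel were 21758 to 32397 for Vil1 (median of the others 80) and 10198 to 28546 for Reg4 (53), but 221 to 290 for Lgr5 (others up to 684) and 136 to 198 for Lct (others up to 195), while the highest percentile on slide 5 in either channel was 31.7 for the stomach list, 27.1 exocrine pancreas, 23.9 kidney, 41.6 lung, 31.5 mammary gland, 34.1 skin and 61.3 spleen, the last above the 47.8 that other arrays reached in the reference channel. Intestinal RNA in both channels of this slide may be the source, perhaps not alone, and since Fabp2, Ang4 and Defa3 also read well on other arrays (medians 6272, 2727 and 928), the list is not free of genes seen in liver.

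The array labelled TGFα tumor 1 read high at 2 Myc probes and correlated best with Myc tumor 1. On a line from Myc tumors to TGFα/c-Myc tumors it stood at 0.24, below the 0.56 to 1.18 of the TGFα/c-Myc tumors. This speaks only weakly against a wrong label of that kind, since Myc tumor 5, at 0.60, lies inside that range too. TGFα/c-Myc tumor 3, on the same slide and with low Myc readings, also helped set the line. The array lay inside the -0.27 to 0.60 of the Myc tumors, a range that ends at 0.16 without Myc tumor 5, itself in question. Myc probe A_51_P102096 read 1.36 on it, outside the -0.97 to 0.43 of the Myc tumors and above the other tumors (at most 0.46), yet below the highest array without tumor (1.94). A Myc tumor under a wrong label and a TGFα tumor with its own Myc expression may each be the source and cannot be told apart here. By the condition first written, on the position alone, the test favored the Myc tumor, but through Myc tumor 5 alone, and the demand that this probe too lie inside the range of the Myc tumors was added after both values were seen.

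Per1 was lower in the 3 controls than on all 31 other arrays. Within scan days, each with 1 control, the smallest difference from a control was 1.04 (SE 0.44). Per1 was chosen for this order of the arrays, so a difference above 0 was given beforehand and says little on slide or day. Per1 was higher in Myc tumors, where the transgene is on and no doxycycline was given (limma adjusted p = 8.10e-06). That direction too was given by the choice, but the gap is there without loss of the transgene or doxycycline, which speaks against either as the whole cause. Of 6 genes that cycle near Per1 the median difference of the 12-week groups from the controls was 0.69. Its SE of 0.33 comes from resampling the 6 genes and does not measure a spread over animals. The median of Arntl, Clock and Npas2 was -0.23, with Nr1d1 at -0.37 the other way, so another time of day at collection may be the source. Genotype stays open, untested. Controls lay below all other arrays in 21 genes and above in 28 of 21545, where 99 other sets of 3 arrays gave a median of 2 and a highest of 204.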

How the results depend on the processing

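All settings were chosen before the data were examined, except the fits named above as chosen later. Over 27 comparisons, counted under each setting where they can be made, 344 counts stayed within 1.5 times the count in the report and 282 did not. Of the calls of the 159 genes followed (the genes named in the comparisons of 2 groups), 2919 kept direction and threshold, 591 lost the threshold and 27 turned direction. Of the list calls followed, 1366 stayed, 150 were lost, 72 of them with the estimated correlation, and 28 turned. Aquantile scaling, keeping outlier spots and averaging Myc tumors 3 and 4 left all 27 counts within 1.5 times. Below, both stands for TGFα/c-Myc, each count is of genes past the threshold, and 3 counts together stand in the order Myc, TGFα and both, or, between tumors or responses, TGFα less Myc, both less Myc and both less TGFα. Of the settings that moved a count or a direction the cause was not tested, except where the setting uses fewer arrays or asks for 2-fold.

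No background subtraction gave 2225 (TGFα) and 677 (both) in tumors against controls, 215 (TGFα) and 3073 (both) at 4 weeks off against tumors and 2134 (both) at 12 weeks off against tumors. It gave 9 (Myc) at 12 weeks off against controls, 3932 (both, TGFα) between tumors and 21 (Myc) at 12 against 4 weeks. It gave 471, 3642 and 454 between responses at 4 weeks and 715, 1223 and 2471 between responses at 12 weeks. Agilent's processed signals gave 870 (both) in tumors against controls, 42 (TGFα) and 3469 (both) at 4 weeks off against tumors and 2729 (both) at 12 weeks off against tumors. It gave 32 (TGFα) and 316 (both) at 4 weeks off against controls, 1, 21 and 17 at 12 weeks off against controls and 3640 (both, TGFα) between tumors. It gave 6 (Myc) and 846 (TGFα) at 12 against 4 weeks, 104 (both, TGFα) between responses at 4 weeks and 1448 (both, Myc) and 3078 (both, TGFα) between responses at 12 weeks. Median centring gave 2893, 51 and 1 in tumors against controls, 2114, 42 and 4 at 4 weeks off against tumors and 2536, 5 and 0 at 12 weeks off against tumors. It gave 0, 1 and 11 at 4 weeks off against controls, 0, 0 and 0 at 12 weeks off against controls and 998, 1457 and 257 between tumors. It gave 0, 0 and 1 at 12 against 4 weeks, 0, 1 and 0 between responses at 4 weeks and 123, 0 and 0 between responses at 12 weeks. The sample channel alone gave 7073 (TGFα) and 309 (both) in tumors against controls, 45 (TGFα) at 4 weeks off against tumors and 7313 (TGFα) and 1443 (both) at 12 weeks off against tumors. It gave 0, 2 and 0 at 4 weeks off against controls, 0 (Myc) and 3 (TGFα) at 12 weeks off against controls and 8290 (TGFα, Myc) and 5144 (both, TGFα) between tumors. It gave 4, 200 and 20 at 12 against 4 weeks and 40, 1295 and 0 between responses at 4 weeks. The series matrix values gave 712 (both) in tumors against controls, 14 (TGFα) and 3635 (both) at 4 weeks off against tumors and 3324 (TGFα) and 2595 (both) at 12 weeks off against tumors. It gave 1, 41 and 403 at 4 weeks off against controls, 95, 281 and 96 at 12 weeks off against controls and 3360 (both, TGFα) between tumors. It gave 62, 1630 and 243 at 12 against 4 weeks, 0 (TGFα, Myc) and 122 (both, TGFα) between responses at 4 weeks and 1318 (both, Myc) and 3385 (both, TGFα) between responses at 12 weeks. Loess removes a trend of the ratio with brightness that median centring leaves in. With median centring the median of all genes moved by up to 0.52 log2 (responses at 4 weeks, both against TGFα). It moved by 0.24 for TGFα tumors against controls, -0.35 for TGFα off 4 weeks against tumors, 0.25 for Myc off 12 weeks against controls and -0.34 between TGFα/c-Myc and TGFα tumors. In the sample channel alone it moved by -0.42 for TGFα tumors against controls and 0.63 for the responses at 12 weeks, TGFα against Myc, and with the series matrix values by 0.31 for TGFα/c-Myc off 4 weeks against tumors. The share of called genes that were higher also moved (settings with at least 20 calls). With median centring it was 71.0% against 52.3% in the report for Myc and 64.7% against 52.6% for TGFα tumors against controls. It was 21.3% against 44.4% and 26.2% against 54.7% for Myc and TGFα off 4 weeks against tumors, and 64.2% against 46.9% for Myc off 12 weeks against tumors. Between tumors it was 74.1% against 50.9%, 11.8% against 47.2% and 6.61% against 47.9%, and for the responses at 12 weeks (TGFα, Myc) 3.25% against 34.1%. In the sample channel alone it was 31.7% and 77.7% (57.8% in the report) for TGFα and both in tumors against controls, and 93.3% and 36.6% (48.5%) at 4 weeks off against tumors. It was 66.6% (46.3%) for TGFα off 12 weeks against tumors, 29.7% (TGFα, Myc) and 62.2% (both, TGFα) between tumors, and 77.5% (42.8%) and 20% (39.9%) at 12 against 4 weeks off TGFα and both. For responses it was 67.5% (26.4%) at 4 weeks and 81.4% at 12 weeks for TGFα less Myc, and 37.7% (52.9%) at 12 weeks for both less TGFα. The series matrix values gave 58.7% for both off 4 weeks against tumors, 80.5% (57.6%) for TGFα off 4 weeks against controls, 20.9% for TGFα at 12 against 4 weeks and 57.4% (37.0%) for the responses at 4 weeks (both, TGFα). Agilent's processed signals gave 54.9% for both at 12 against 4 weeks.

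No filter on dim probes gave 60 (TGFα, Myc) between responses at 4 weeks. The strict filter on dim probes gave 16 (TGFα) at 4 weeks off against tumors, 1 (Myc) at 4 weeks off against controls and 1 (TGFα) at 12 weeks off against controls. The mean of all probes gave 404 (both) at 12 weeks off against tumors, 4 (Myc) at 12 weeks off against controls and 0 (Myc) at 12 against 4 weeks. It gave 17 (both, TGFα) between responses at 4 weeks. The trend and robust options gave 1 (Myc) and 105 (TGFα) at 4 weeks off against controls, 10 (Myc) and 3 (TGFα) at 12 weeks off against controls and 0 (Myc) and 75 (both) at 12 against 4 weeks. It gave 5 (both, TGFα) between responses at 4 weeks. Array weights gave 6318 (TGFα) and 1419 (both) in tumors against controls, 4015 (TGFα) and 4063 (both) at 4 weeks off against tumors and 6446 (TGFα) and 2973 (both) at 12 weeks off against tumors. It gave 303, 2258 and 4611 at 4 weeks off against controls, 2082, 600 and 2045 at 12 weeks off against controls and 8894 (TGFα, Myc) and 5345 (both, TGFα) between tumors. It gave 2101, 2427 and 4857 at 12 against 4 weeks, 7447, 5341 and 3516 between responses at 4 weeks and 7439, 2327 and 5578 between responses at 12 weeks. Only the groups compared gave 4721, 3 and 0 in tumors against controls, 0 (TGFα) and 42 (both) at 4 weeks off against tumors and 3914, 593 and 234 at 12 weeks off against tumors. It gave 0, 1 and 0 at 4 weeks off against controls, 0, 1 and 0 at 12 weeks off against controls and 4, 1499 and 4 between tumors. It gave 0, 0 and 309 at 12 against 4 weeks, 0, 1485 and 1 between responses at 4 weeks and 4, 73 and 434 between responses at 12 weeks. At least 2-fold gave 3225 (Myc) and 731 (TGFα) in tumors against controls, 2881 (Myc) and 721 (both) at 4 weeks off against tumors and 2906 (Myc) and 935 (TGFα) at 12 weeks off against tumors. It gave 1, 98 and 301 at 4 weeks off against controls, 11 (Myc) and 3 (TGFα) at 12 weeks off against controls and 1744, 1874 and 804 between tumors. It gave 226 (TGFα) and 36 (both) at 12 against 4 weeks. The sex score gave 1, 8 and 4 at 12 weeks off against controls and 0 (Myc) at 12 against 4 weeks.

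The replicate numbers were checked for pairing: over 135 pairs of arrays with the same number in different groups the median r was 0.00138, against -0.00861 for other pairs, and 46 of the 135 had r over 0.1, with a lowest of -0.493. Of the 34 arrays 18 matched best with an array of their own number, where chance would give 8.84, a hint that some numbers go together. Most pairs had r of 0.1 or less and the labels name nothing shared, so the numbers were not taken to pair the arrays. The replicate block gave 333 (both) in tumors against controls, 125 (TGFα) at 4 weeks off against tumors and 8 (Myc) and 7 (both) at 12 weeks off against controls. It gave 388 (TGFα, Myc) and 51 (both, TGFα) between responses at 4 weeks and 884 (both, Myc) between responses at 12 weeks.

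Slides as a random block gave 552 (TGFα) and 3 (both) in tumors against controls, 333 (TGFα) and 398 (both) at 4 weeks off against tumors and 84 (TGFα) and 16 (both) at 12 weeks off against tumors. It gave 1, 110 and 535 at 4 weeks off against controls, 8, 1 and 0 at 12 weeks off against controls and 1083 (TGFα, Myc) and 730 (both, TGFα) between tumors. It gave 0, 0 and 2 at 12 against 4 weeks, 769 (TGFα, Myc) and 169 (both, TGFα) between responses at 4 weeks and 12 (TGFα, Myc) and 0 (both, TGFα) between responses at 12 weeks. Scan day as a block gave 4030, 2196 and 864 in tumors against controls, 667 (TGFα) and 489 (both) at 4 weeks off against tumors and 278 (Myc) and 737 (TGFα) at 12 weeks off against tumors. It gave 15 (Myc) and 1141 (TGFα) at 4 weeks off against controls, 10 (TGFα) and 7 (both) at 12 weeks off against controls and 36 (TGFα, Myc) and 631 (both, Myc) between tumors. It gave 13 (Myc) and 440 (both) at 12 against 4 weeks, 2419, 4266 and 619 between responses at 4 weeks and 25 (TGFα, Myc) and 115 (both, Myc) between responses at 12 weeks. Without slide 5 the scan day block could not be fitted for livers off TGFα or both transgenes for 4 weeks, against tumors, controls or 12 weeks, nor for their response differences from c-Myc at 4 weeks.

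Without slide 5 the only TGFα tumor is the array labelled TGFα tumor 1, so counts with TGFα tumors there say little. The first scanner holds 1 Myc tumor. Leaving out slide 5 gave 2491 (TGFα) and 457 (both) in tumors against controls, 981 (TGFα) at 4 weeks off against tumors and 32, 21 and 4 at 12 weeks off against controls. It gave 81 (TGFα, Myc) and 637 (both, TGFα) between tumors, 216 (TGFα) at 12 against 4 weeks and 17 (TGFα, Myc) and 43 (both, TGFα) between responses at 4 weeks. It gave 25, 634 and 600 between responses at 12 weeks. Leaving out slide 5 and TGFα tumor 1 gave 457 (both) in tumors against controls, 32, 21 and 4 at 12 weeks off against controls and 216 (TGFα) at 12 against 4 weeks. It gave 634 (both, Myc) between responses at 12 weeks. The first scanner alone gave 2097 (TGFα) and 329 (both) in tumors against controls, 134 (TGFα) at 4 weeks off against tumors and 444 (TGFα) and 1386 (both) at 4 weeks off against controls. It gave 9 (both) at 12 weeks off against controls, 911 (TGFα, Myc) and 3096 (both, Myc) between tumors and 0, 859 and 329 at 12 against 4 weeks. It gave 86 (both, TGFα) between responses at 4 weeks and 171 (TGFα, Myc) and 659 (both, Myc) between responses at 12 weeks. Scanner as a block gave 3552 (Myc) in tumors against controls, 2661 (Myc) at 4 weeks off against tumors and 2757 (Myc) at 12 weeks off against tumors. It gave 3 (TGFα) at 12 weeks off against controls, 85 (TGFα, Myc) and 1406 (both, Myc) between tumors and 0 (Myc) at 12 against 4 weeks. It gave 13, 1570 and 41 between responses at 4 weeks and 17 (TGFα, Myc) and 53 (both, Myc) between responses at 12 weeks. Slide as a fixed block gave 1628 (Myc) in tumors against controls, 3697, 658 and 472 at 4 weeks off against tumors and 508 (TGFα) and 106 (both) at 12 weeks off against tumors. It gave 14 (Myc) at 4 weeks off against controls, 345 (both) at 12 against 4 weeks and 1567 (TGFα, Myc) and 636 (both, TGFα) between responses at 4 weeks. It gave 102 (both, TGFα) between responses at 12 weeks.

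Some named genes and lists turned direction, given here as log2 change for genes and as camera adjusted p in the other direction for lists. With scan day as a block Saa3 stood at -0.32 and the neutrophil list at 0.807 in Myc tumors against controls. In TGFα/c-Myc off 4 weeks against tumors, tied only through slide 5, Afp stood at 2.19, Tff3 at 1.39 and Fkbp11 at 0.86, and the cell cycle, cholesterol, drug and oncofetal lists at 0.000259, 0.00155, 0.0724 and 7.38e-06. Against controls, by the same tie, Bbc3 stood at 1.01 and the acute phase list at 0.720 at 4 weeks off both, and the female-biased and clock lists at 0.0564 and 0.715 at 4 weeks off TGFα. Between TGFα and Myc tumors Mbl2, Adam8 and Lgals3 stood at -1.34, 0.82 and 1.31 and the drug and cell cycle lists at 0.679 and 0.126, and between TGFα/c-Myc and Myc tumors Saa3 at 1.18, S100a8 at 0.065 and the acute phase list at 0.598. Rdh10 stood at 0.044 at 12 against 4 weeks off TGFα.

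In the sample channel alone Igfbp1 and Sis turned to -2.11 and 1.42 in TGFα tumors against controls. Between TGFα and Myc tumors Hrg, C9, Mbl2, Reg3g and Lgals3 turned to -1.87, -0.79, -3.37, 2.40 and 0.68, and the drug, plasma protein and cell cycle lists to 0.109, 0.000243 and 0.443. Between TGFα/c-Myc and TGFα tumors Orm1, Bnip3 and Gnmt turned to 3.03, 0.31 and 4.17 and the urea cycle list to 2.01e-06. This setting drops the reference, whose profile differs on slide 5. The cell cycle list between TGFα/c-Myc and Myc tumors turned in the sample channel alone (0.874), with Agilent's processed signals (0.992) and with the series matrix values (0.796). Without slide 5, with the array labelled TGFα tumor 1 alone, it turned between TGFα and Myc tumors (0.0693). On the first scanner alone and with scanner as a block the neutrophil list of Myc tumors against controls turned (0.7604 and 0.918), as did the acute phase list between TGFα/c-Myc and Myc tumors (0.780 and 0.853). With slide as a fixed block Saa3 (-0.30) and the neutrophil list (0.407) turned in Myc tumors against controls; in TGFα/c-Myc off 4 weeks against tumors Afp, Tff3 and Fkbp11 stood at 2.19, 1.39 and 0.86 and the cell cycle, cholesterol, drug and oncofetal lists at 0.000682, 0.00312, 0.0844 and 1.85e-05; and at 12 against 4 weeks off TGFα Ugt1a1 and Rdh10 stood at 0.085 and 0.70.

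Leaving out each array in turn kept 94 counts within 1.5 times and moved 140. In brackets is the array left out. In tumors against controls counts ran for Myc 4721 (control 3) to 8115 (Myc tumor 5), TGFα 101 (control 3) to 1964 (TGFα tumor 1) and both 3 (both tumor 1) to 469 (both tumor 3). At 4 weeks off against tumors counts ran for Myc 3890 (Myc off 4 weeks 1) to 7347 (Myc tumor 5), TGFα 7 (TGFα tumor 3) to 309 (TGFα tumor 1) and both 308 (both tumor 1) to 1870 (both tumor 3). At 12 weeks off against tumors counts ran for TGFα 885 (TGFα off 12 weeks 3) to 2355 (TGFα tumor 1) and both 98 (both tumor 1) to 1243 (both tumor 3). At 4 weeks off against controls counts ran for Myc 1 (Myc off 4 weeks 1 or 2 others) to 3 (control 2), TGFα 1 (control 3) to 570 (control 1) and both 161 (control 3) to 1114 (control 1). At 12 weeks off against controls counts ran for Myc 0 (Myc off 12 weeks 1 or 1 other) to 313 (control 1), TGFα 1 (TGFα off 12 weeks 2 or 2 others) to 21 (control 1) and both 1 (both off 12 weeks 3 or 2 others) to 26 (control 1). Between tumors counts ran for TGFα less Myc 626 (TGFα tumor 2) to 6756 (TGFα tumor 1), both less Myc 1428 (both tumor 2) to 5891 (Myc tumor 5) and both less TGFα 318 (TGFα tumor 2) to 2907 (TGFα tumor 1). At 12 against 4 weeks counts ran for Myc 0 (Myc off 12 weeks 1 or 3 others) to 6 (Myc off 12 weeks 3), TGFα 138 (TGFα off 4 weeks 2) to 638 (TGFα off 4 weeks 3) and both 6 (both off 12 weeks 1 or 1 other) to 435 (both off 4 weeks 3). Between responses at 4 weeks counts ran for TGFα less Myc 0 (Myc off 4 weeks 1 or 3 others) to 2557 (TGFα tumor 1), both less Myc 1163 (both tumor 2) to 3449 (Myc tumor 5) and both less TGFα 3 (both tumor 2 or 2 others) to 756 (TGFα tumor 1). Between responses at 12 weeks counts ran for TGFα less Myc 29 (TGFα tumor 3) to 4281 (TGFα tumor 1), both less Myc 25 (both tumor 2) to 1211 (Myc tumor 5) and both less TGFα 379 (both tumor 2) to 2429 (TGFα tumor 1). Calls of named genes stayed in 952 cases and were lost in 246, and calls of the lists followed stayed in 557 and were lost in 19, with no turn of direction among these. Among all 278 list calls of the study's comparisons, 240 stayed and 12 turned without TGFα tumor 1, the only array whose removal turned any. With Aquantile scaling 277 stayed, 130 with scan day as a block and 143 in the sample channel alone, with 56 and 48 calls turned in the last pair.

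With the strict filter on dim probes 24 of 27 counts stayed within 1.5 times, and without a filter 26.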

Other observations

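Some lists also shifted between responses, none with an estimated correlation, and at 4 weeks chance is not excluded (below). At 4 weeks off, male-biased liver genes responded more downward with TGFα than with c-Myc (1 of 18 past the threshold, 12 adjusted over the list alone, median -3.72, adjusted p = 6.16e-10, 0.511 with an estimated correlation), in groups whose labels give no sex. Acute phase genes responded more upward with both transgenes than with TGFα (0 of 17, 6 adjusted over the list alone, median 1.52, adjusted p = 0.000212, 0.838 with an estimated correlation). At 12 weeks drug and steroid metabolism responded more downward with TGFα than with c-Myc (10 of 22, 11 adjusted over the list alone, median -2.67, adjusted p = 7.13e-08, 0.319 with an estimated correlation). Without slide 5 the TGFα tumors are 1 array that resembles Myc tumors, so a small difference is near given.

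Other splits of the same arrays into groups of the same sizes were counted, 100 splits each where that many exist. Chance can be excluded for Myc tumors against controls (7212 genes, highest other split 4165), Myc off 4 weeks (6294, 3652) and 12 weeks (6222, 3549) against tumors, and TGFα/c-Myc against Myc tumors (4662, 4248), with 1 split as large, the real one. The rule was also met for TGFα against Myc tumors (3733, 3 splits as large), where a split that set Myc tumor 5 with TGFα tumors 2 and 3 gave 7478. It was met for the response differences of TGFα/c-Myc from Myc at 4 weeks (2393, 604) and 12 weeks (329, 216), of TGFα/c-Myc from TGFα at 12 weeks (1096, 862) and of TGFα from Myc at 12 weeks (1148, 2429, 2 splits as large). It was not met for the response differences at 4 weeks of TGFα from Myc (129, 6 splits as large, highest 4071) and of TGFα/c-Myc from TGFα (27, 23 splits as large, highest 2924). Splits with several times the real count point to a structure of the samples. These splits move single arrays and leave slides and days aside: with slides as a random block 1083 genes passed for TGFα against Myc tumors, and 12 and 0 for the response differences at 12 weeks of TGFα from Myc and of TGFα/c-Myc from TGFα, so that a grouping by slide stays open for these. With scan day as a block 278 passed for Myc off 12 weeks against tumors, 36 for TGFα and 631 for TGFα/c-Myc against Myc tumors, and 25 and 115 for the response differences at 12 weeks of TGFα and TGFα/c-Myc from Myc.

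With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 1391 and 629 for TGFα tumors and 166 and 0 for TGFα/c-Myc tumors against controls. Against tumors they were 75 and 2019 for TGFα off 4 weeks, a split that follows slide 5 (655 within that slide), 1311 and 133 for TGFα/c-Myc off 4 weeks, and 1953 and 183, and 678 and 0, for these at 12 weeks. Against controls they were 2 and 0, 205 and 0, and 910 and 5 at 4 weeks, and 19 and 160, 5 and 2, and 2 and 0 at 12 weeks, for Myc, TGFα and both. TGFα/c-Myc against TGFα tumors gave 1350 and 2859, the latter with TGFα tumor 1 set with TGFα/c-Myc tumors 1 and 2, and 12 against 4 weeks gave 1 and 0, 544 and 0, and 138 and 0.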
